A study of Rattus norvegicus with 3 samples.

How the data were processed

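Messenger RNA was measured in skeletal muscle of 12-week-old male rats of a Wistar background (Wistar Honnover per the labels) on 3 one-colour (Cy3) Agilent expression arrays. One array held RNA of the normal soleus, 1 the soleus 28 days after transection of the left sciatic nerve (about 5 mm), and 1 the normal plantaris. The normal soleus array carries only the word Post as its title and was placed by its source name. The number of animals behind each array is not given in the sources used here. With 1 array per group there are no replicates, so no p-value, SD across samples or confidence interval is given for any gene.

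Per the file headers, the arrays were scanned and quantified with Agilent Feature Extraction 10.10.1.1, and the processed signal is an intensity on a linear scale, background-subtracted and detrended across the array by that software, with no normalization between arrays. Per the file headers, the files also hold raw spot and local background intensity, and other columns of flags of 0 or 1 for spots that are well above background, saturated or outliers. The authors' deposited value table is an intensity too. Set against the scanner signals it equalled the processed signal times 1 factor per array, 1.60 for normal soleus, 1.41 for denervated soleus and 1.80 for plantaris, and what set the factors is not given in the sources used here. Probe names were joined to gene symbols through their RefSeq accessions, since the files hold no gene column. Of 30367 probes, 18005 carried a gene symbol, standing for 15168 genes, and 12362 did not and were left out of the comparisons. The array design was drawn up on an older rat assembly than the reference used for the names, so no gene positions are printed.

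The log2 processed signal of each spot was centred on the 75th percentile of the 58717 non-control spots of its array. Between 467 and 569 spots per array bore an outlier flag and were left out, and 0 were saturated. Repeat spots of a probe were averaged, and a probe counted as well above background where at least 50 percent of its spots did. The brightest probe stood for a gene with several probes, and a gene named here is given with the values of its other probes where these were well above background on both arrays and differed by over 1 log2 unit, or in sign by over 0.5. A gene entered a comparison if it was well above background on at least 1 of the 2 arrays. Where it was so on 1 array only, its fold is called a bound and is written with "at least". It is taken against the larger of the other array's own signal and the faintest signal well above background there. Where the own signal is the larger, the bound is the plain difference from a faint signal, and other processing can give a smaller one. Counts take genes at least 2-fold apart (1 log2 unit), a rule on size and not a test.

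The median log2 fold of each of 30 gene lists was placed among the medians of 10000 random lists of the same size, matched in 20 bins of brightness, and a list is said to stand apart at or below the 2.5 or at or above the 97.5 percentile. This describes these arrays and is not a test across animals. The lists, the comparisons, the first set of alternatives and the rule for named genes were fixed before the data were examined. That rule takes, per comparison and direction, the 6 largest folds among genes measured on both arrays and the 4 largest bounds. It adds up to 4 members of each list with the largest folds, any member past 2-fold against its list's median, and 15 genes whatever their value, among them the myosin heavy chains and acetylcholine receptor subunits. A gene named outside the rule is said to have been chosen after its value was seen.

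Errors are technical. The scanner software's signal errors give a median of 0.205 log2 units per fold. Repeat spots of a probe differed with an SD of 0.365 log2 units on the normal soleus array, 0.274 on the denervated and 0.230 on the plantaris array, mostly from faint probes. Of the 30367 probes, 64.2% were well above background on the normal soleus array, 67.0% on the denervated and 65.3% on the plantaris array. In simulated data with the measured repeat-spot noise, 195 of 200 planted changes of 1.5 or 2 log2 units either way were recovered. Smaller changes were not planted. Of 10291 unchanged genes 350 (3.4%) passed 2-fold, of which 2 came from the 7577 genes that were not faint. Of 400 unchanged lists 21 (5.2%) stood apart. These lists were drawn at random from the same genes as the random lists, so this share checks the procedure only. It gives no rate for lists of genes that vary together. Noise in these simulated data and in the simulated overlap first used an assumed or pooled SD. It was changed to the SD measured by brightness after the first values were seen.

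The normal soleus and plantaris arrays lie on 1 slide and were scanned together, and the denervated array lies on another. Any difference between slides or scans therefore cannot be told apart from denervation. The comparisons were normal plantaris over normal soleus, denervated over normal soleus, and the overlap of their genes. Alternatives were normexp background correction with an offset of 50, quantile normalization, the 75th percentile over detected probes only, a stricter filter and none, the authors' values, the mean of a gene's probes, thresholds of 1.5-fold and 4-fold, and random lists matched on size alone. The normexp correction was planned on the mean spot signal, which the files lack, and used the median spot signal. Leaving out bright patches of an array and keeping only probes whose repeat spots agree within 0.5 log2 units were added after seeing the data. A spot lies in a bright patch where its 12 nearest faint spots exceed the other arrays by a median of over 1 log2 unit. The authors' factors move the median fold of all genes from 0.02 to 0.26 in denervated over normal soleus and from 0.02 to -0.08 in plantaris over normal soleus. Work was done in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and in R 4.3.3 with limma 3.58.1 for normexp. A few genes that the rule for named genes takes are not reported here.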

Results

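The study set a fast limb muscle against a slow one, and a slow muscle that had lost its nerve against the normal one. Messenger RNA of 3 rat calf muscles was measured on 3 arrays, 1 each for the normal soleus, a slow postural muscle, the normal plantaris, a faster neighbour, and the soleus 28 days after the sciatic nerve was cut. Each array held 58717 non-control spots for 30367 probes, and between 64.2% and 67.0% of the probes were well above background. There are no replicates, so every fold describes these arrays, and the number of arrays limits what can be said about other animals. Errors given with a fold (±) come from the scanner software and cover measurement only. Folds are in log2 units, so 1 unit is 2-fold.

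**Figure D1:**
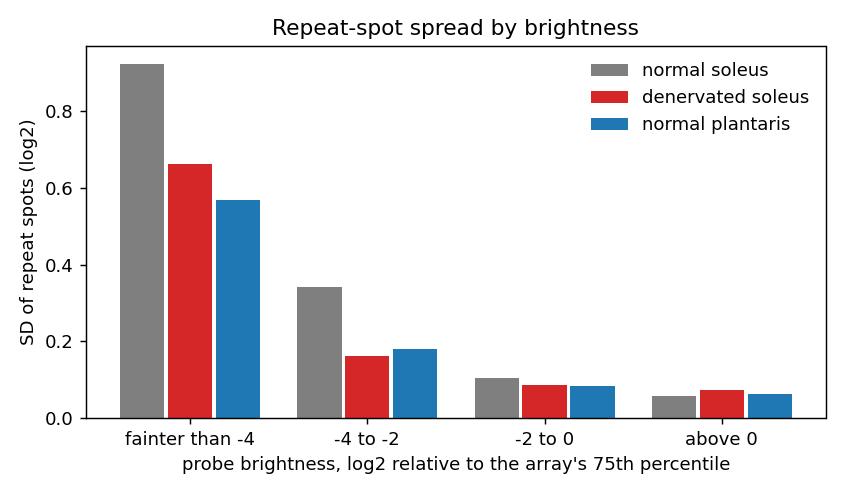
SD of repeat spots of the same probe (log2 units, vertical axis) in 4 classes of probe brightness relative to the array's 75th percentile (horizontal axis), with 1 bar per array. Probes fainter than -4 spread most, with an SD of 0.924 on the normal soleus array, and probes above 0 least, with 0.057 there.

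The first comparison, plantaris over soleus, asks how a fast muscle differs from a slow one. The largest difference was in Actn3, the alpha-actinin of fast fibre Z-discs, which was 770-fold higher on the plantaris array (9.59 ± 0.20). Pvalb, the calcium buffer of fast fibres, was higher by 8.20 ± 0.20, and Myh1 and Myh4, the IIx and IIb myosin heavy chains, by 7.37 ± 0.20 and 7.22 ± 0.20. In the other direction Myh7, the slow myosin heavy chain, stood at -2.62 ± 0.20. Among 11015 genes, 629 were at least 2-fold higher and 673 at least 2-fold lower in plantaris.

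All 13 measured members of the slow fibre list were at least 2-fold lower in plantaris (median -2.64), among them Ankrd2, a titin-binding stress sensor (-4.28), the slow myosin light chain Myl2 (-3.54), the myosin Myh7b (-3.39) and the slow troponin I Tnni1 (-3.19). Of 14 fast fibre members 13 were at least 2-fold higher (median 2.36). The remaining one was the IIa myosin Myh2 at 0.98 ± 0.20. Of 8 measured developmental and cardiac sarcomere genes 6 were lower and 2 higher (median -2.27). Cardiac actin Actc1 stood at -2.75, embryonic myosin Myh3 at -2.74 and the atrial light chain Myl4 at -2.41, and cardiac troponin I Tnni3 was lower by a log2 bound of -3.12. Perinatal myosin Myh8 went the other way at 1.22, or 0.95 under quantile normalization, and Ankrd1 was just at the threshold with 1.0, below it in 4 alternatives.

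Glycolysis was the broadest metabolic difference. Of 23 genes for glycolysis and glycogen 20 were at least 2-fold higher in plantaris (median 2.16), led by the gluconeogenic Fbp2 (3.47), glycerol-3-phosphate dehydrogenase Gpd1 (3.41), pyruvate kinase Pkm (2.73) and the phosphorylase kinase subunit Phka1 (2.66). The glycogen branching enzyme Gbe1 was the 1 lower member (-1.01, or -0.85 with normexp background). Of 22 genes for fatty acid uptake and oxidation 4 were lower and 1 higher (median -0.71). Lipoprotein lipase Lpl stood at -2.44, the fatty acid carrier Fabp3 at -1.80 and Eci1 at -1.18, against 1.47 for the uncoupling protein Ucp3. Mitochondrial genes differed little. No member of 20 in the respiratory chain list passed 2-fold, with a median of 0.11 that turned to -0.17 under quantile normalization. Of 17 tricarboxylic acid cycle genes only Idh3a did (1.98), with a list median of 0.14 that turned to -0.02 there. Of 13 oxidative regulators only Esrrg did (-1.25 ± 0.36, or -0.41 with normexp background; list median -0.03). Myoglobin, Mb, stood at -0.03 and the coactivator Ppargc1a at 0.61.

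**Figure D2:**
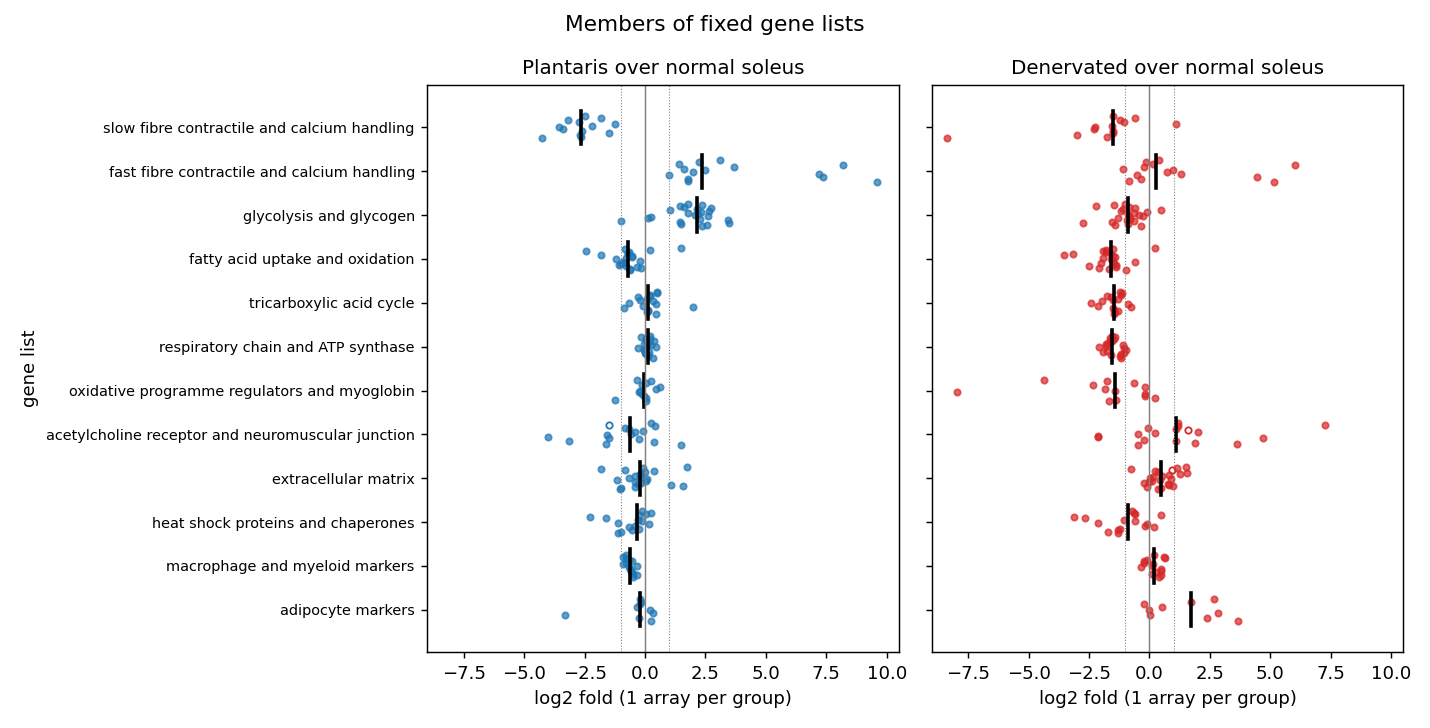
Log2 fold (horizontal axis) of each measured member of 12 of the 30 gene lists in plantaris over normal soleus (left) and denervated over normal soleus (right), 1 array per group. Points are genes, open where the fold is a bound, black bars are list medians and dotted lines mark 2-fold. The respiratory chain list lies at a median of 0.11 on the left (-0.17 under quantile normalization) and -1.54 on the right.

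Of 16 excitation-contraction coupling genes 5 were higher in plantaris (median 0.67), among them the chloride channel Clcn1 (1.57), the sodium channel Scn4a (1.24, or 0.95 with normexp background) and the calcium channel Cacna1s (1.1, or 0.85 under quantile normalization). Against them Sln, which encodes the calcium pump inhibitor sarcolipin, stood at -4.38 ± 0.20. The acetylcholine receptor and junction list leaned to soleus, with 6 of 16 members lower in plantaris and 1 higher (median -0.61). Colq, which anchors acetylcholinesterase at the synapse, stood at -4.01 ± 0.27 and the receptor subunit Chrnd at -3.16, whereas the enzyme itself, Ache, was at 1.49. The receptor subunits Chrna1, Chrng and Chrne stood at -1.59, -1.49 and -0.24, and Dok7 at -1.59. Of 13 myogenic and activity-dependent factors Myod1 was higher (2.03) and Myog lower (-1.64). Their list median of -0.16 turned to 0.03 with normexp background. Of 13 fibre type regulators Sox6, a repressor of slow fibre genes, was at 2.88 ± 0.32 and Maf at 2.42, and Rcan1 was lower at -2.02 (median 0.28). Myostatin, Mstn, was at least 3.19 higher in plantaris, but with an error of 1.46.

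The extracellular matrix list had 3 of 22 members higher and 3 lower (median -0.22). Tenascin Tnc stood at 1.73 ± 0.33 (0.87 with normexp background) and collagen Col1a1 at 1.59, against -1.82 for Timp1. Of 16 heat shock genes 4 were lower (median -0.35), namely the small heat shock proteins Hspb7 (-2.28), Hspb6 (-1.60) and Hspb1 (-1.11) and their partner Bag3 (-1.12). None of 15 macrophage markers passed 2-fold, but all 15 lay below 0 (median -0.62), as did all 7 blood cell markers (median -0.47). The cell cycle list (11 genes, 1 lower, median -0.52) rested in part on faint genes and no longer stood apart with genes well above background on both arrays. Its 1 lower gene, Ccna2, was at -3.16 as a bound on 1 probe and -0.31 on another. The clock list (14 genes, 1 higher, median 0.36) no longer stood apart with a mean over probes. Its Per3 was at 2.36 on 1 probe and 0.14 and -0.20 on others.

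Of the 30 lists 13 stood apart, namely 9 to the low side (slow fibre, developmental, fatty acid, junction, extracellular matrix, heat shock, cell cycle, macrophage and blood cell lists) and 4 to the high side (fast fibre, glycolysis, coupling and clock lists). The other 17 stood within the range of random lists, the mitochondrial and regulator lists above among them. Their remaining medians were 0.05 for 15 atrophy ligase and FoxO genes (Gadd45a -1.06, or -0.91 with normexp background, Trim63 0.82, Fbxo32 -0.06), 0.17 for 31 proteasome subunits, none past 2-fold, and 0.00 for 21 autophagy genes, none past 2-fold. Growth factor and myostatin signalling had a median of 0.00 over 17 genes, 1 higher and 2 lower, and immediate early genes 0.08 over 15, with Nr4a3 and Nr4a1 higher (at least 2.31, or 0.97 with normexp background, and 1.62) and Ier3 lower (-1.36). The medians of the atrophy, autophagy, growth factor and immediate early lists changed sign with the authors' values. Among cell types, the median was -0.48 for 7 lymphocyte markers (1 lower; 0.08 among agreeing repeat spots), -0.27 for 10 endothelial markers (Cdh5 -1.71), -0.24 for 12 smooth muscle and pericyte markers (2 higher) and -0.11 for 9 fibroblast and tendon markers (Fmod 1.36). It was -0.20 for 9 adipocyte markers (Cidea -3.32), 0.08 for 11 Schwann cell and nerve markers (-0.03 with the authors' values) and -0.13 for 13 reference genes (Eef1a1 -1.07).

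Beyond the lists, Ostn, which encodes the secreted muscle peptide musclin, was at 6.03 ± 0.26 and Mss51 at 5.89 ± 0.20 in plantaris. Fhl2, a LIM domain protein, stood at -4.63 ± 0.29, the anion exchanger Slc4a3 at -4.06 ± 0.20 and Epn3 at -4.04 on 1 probe and -1.16 on another. Genes measured on 1 array only give bounds. Tpx2, a spindle protein, was at least 5.80 higher in plantaris, Iqcg 4.59, Virma 4.44 and Adgrb2 4.29. Toward soleus the largest bounds were -4.81 for Gjd2, -4.08 for Ropn1, -4.02 for Magea13 and -3.94 for Sertm1, and Virma and Gjd2 lay in bright patches of an array. With normexp background the counts fell to 309 higher and 282 lower genes, and among genes measured on both arrays they were 439 and 433.

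The second comparison, denervated over normal soleus, asks how a slow muscle differs after 28 days without its nerve. Genes of mitochondrial energy supply were lower as a block. Of 20 respiratory chain and ATP synthase genes 19 were at least 2-fold lower (median -1.54), as were 15 of 17 tricarboxylic acid cycle genes (median -1.45) and 19 of 22 fatty acid genes (median -1.60). Acetylcholine receptor subunits stood out on the high side, Chrng, the fetal subunit, by 4.71 ± 0.20 and Chrna1 by 3.62 ± 0.20, whereas Chrne, the adult subunit, was at -0.24 ± 0.21. Among 11318 genes, 988 were at least 2-fold higher and 1518 at least 2-fold lower in the denervated muscle.

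In the mitochondrial lists cytochrome c, Cycs, stood at -2.08, Cox5a at -1.91, Ndufa9 at -1.80 and Ndufs1 at -1.78. Malate dehydrogenases Mdh1 and Mdh2 were at -2.41 and -1.97, Idh3b at -2.14 and Sdhc at -1.75. In fatty acid oxidation Fabp3 stood at -3.54, Hadh at -3.14, Acsl1 at -2.50 and Acadm at -2.07. Of 13 oxidative regulators 8 were lower (median -1.42), and Perm1, a muscle regulator of mitochondrial genes, was among the genes with the lowest folds at -7.95 ± 0.29. Vegfb stood at -4.34 and Ppargc1b at -2.35, while Ppard was at -1.83 on 1 probe and -0.22 on another. Ppargc1a (-0.19 ± 0.21) and myoglobin Mb (-0.18 ± 0.20) lay within their error of 0. On the same array fat cell markers had a median of 1.70 and fibroblast and tendon markers of 0.80. Of 23 glycolysis and glycogen genes 8 were lower and none higher (median -0.87), with Fbp2 at -2.77, Ppp1r3c at -2.20, Gapdh at -1.57 and Pygm at -1.46.

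Slow fibre genes were lower too, 11 of 13 past 2-fold and 1 higher (median -1.5). Ankrd2 had the lowest fold of any gene measured on both arrays (-8.38 ± 0.21), and Casq2 stood at -2.98, Myh7b at -2.29 and Myl2 at -2.24. Myh7 was at -1.5, or -0.77 under quantile normalization, and phospholamban, Pln, was higher by 1.11. Fast fibre genes split. Pvalb was higher by 6.02, Actn3 by 5.14, Myh1 by 4.43 and Myh4 by 1.30, each ± 0.20, whereas the kinase Mylk2 was at -1.11 (-0.89 under quantile normalization) and Myh2 at -0.52, with 9 of 14 members within 2-fold. The fast fibre median of 0.27 stood apart from lists matched on brightness (percentile 99.97) but not from lists matched on size alone (percentile 87.8). Of 8 developmental and cardiac sarcomere genes 3 were higher and 3 lower, and their median of -0.32 turned to 0.29 under quantile normalization. Ankrd1, a stress-induced titin partner, was at 4.37, cardiac troponin T Tnnt2 at 1.80 and Myh3 at 1.5, against -1.88 for Tnni3, -1.62 for Myl4 and -0.51 for Myh8.

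**Figure D3:**
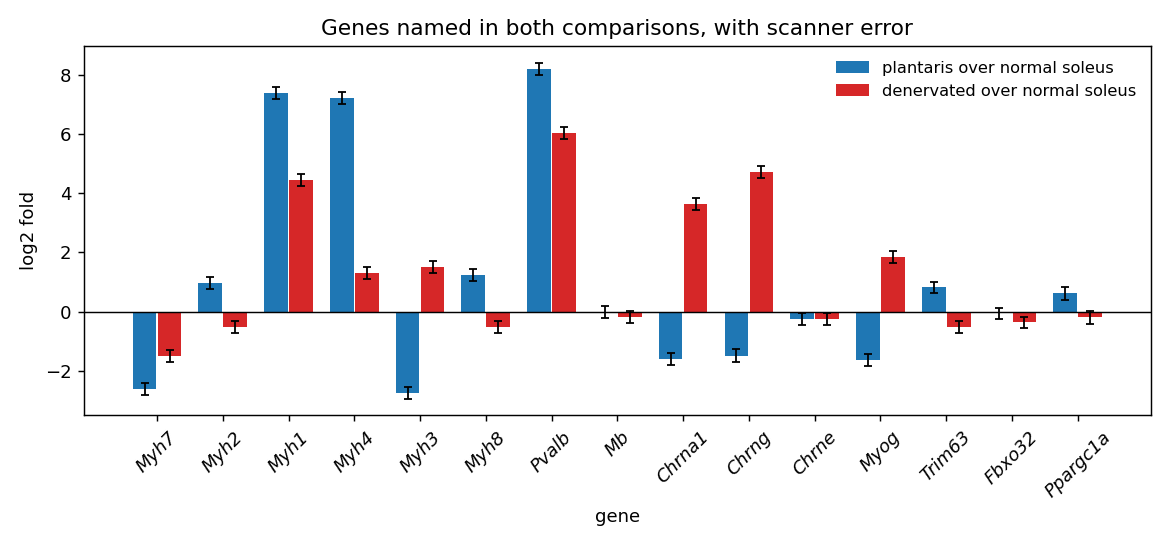
Log2 fold (vertical axis) of the 15 genes named in both comparisons whatever their value, in plantaris (blue) and denervated soleus (red) over normal soleus, with the scanner error as bars. Chrng stands at -1.49 in plantaris and 4.71 in denervated soleus, and Myh1 at 7.37 and 4.43.

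Of 17 acetylcholine receptor and junction genes 10 were higher and 2 lower (median 1.1). The lower ones were Colq (-2.13) and Dok7 (-2.11). Of 14 myogenic and activity-dependent factors 4 were higher and 2 lower (median 0.53), with Myod1 at 4.34, Runx1 at 3.24, Id2 at 2.25 and Myog at 1.86. Mef2d stood at -1.42 and Hdac9 at a bound of -2.08, which was -0.80 with normexp background. Of 15 atrophy ligase and FoxO genes 3 were higher and 1 lower (median 0.24), namely Gadd45a (3.16), the ubiquitin ligases Nedd4 (1.29) and Fbxo30 (1.22, or 0.94 with normexp background), and Cdkn1a, whose probes stood at -1.04 and 5.33. The ligases Trim63 and Fbxo32 were at -0.53 and -0.36, each ± 0.20. None of 31 proteasome subunits passed 2-fold, and their median of -0.10 turned to 0.14 with the authors' values. Growth factor genes were higher in 6 of 17 (median 0.44), led by Fst, the myostatin antagonist follistatin (2.86), Igfbp5 (1.93), Mstn (at least 1.80 ± 1.47, or 0.35 with normexp background) and Igfbp4 (1.33).

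Matrix genes were higher in 4 of 23 (median 0.49), namely Postn (1.54), Tnc (1.52, or 0.54 with normexp background), Mmp2 (1.25) and Timp2 (1.15). Fibroblast and tendon markers were higher in 2 of 9 (median 0.80), Comp by 2.77 and Fmod by 2.11. Adipocyte markers were higher in 5 of 9 (median 1.70), with the hormone adiponectin, Adipoq, at 3.65, Cidec at 2.83 ± 0.31, Retn at 2.68 and Cfd at 2.40. Of 16 heat shock genes 8 were lower (median -0.90), with the small heat shock proteins Hspb7 at -3.14, Hspb6 at -2.65, Hspb1 at -2.12 and Cryab at -1.71. Smooth muscle and pericyte markers had a median of -0.56 with 1 of 11 past 2-fold, no longer apart from lists matched on size alone (percentile 2.71). Endothelial markers were not apart (median -0.48, percentile 2.71), although Cdh5 (-2.30), Kdr (-1.39) and Flt1 (-1.29, or -0.96 with normexp background) were lower. Schwann cell and nerve markers moved both ways, 4 higher and 5 lower of 14, with a median of -0.18 that turned to 0.01 with the authors' values. The myelin gene Mbp stood at -2.11 on 1 probe but at least 1.36 higher on another, while S100b was at 2.21 (0.01 on a probe above background on neither array), Cnp at 2.06 and the neurotrophin receptor Ngfr at least at 1.80 (0.39 with normexp background).

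Of the 30 lists 16 stood apart, 8 low (the slow fibre, 3 mitochondrial, oxidative regulator, glycolysis, heat shock and smooth muscle lists) and 8 high (the fast fibre, junction, myogenic, growth factor, matrix, fibroblast, adipocyte and reference gene lists). The reference genes, chosen as genes often taken as stable, had a median of 0.20, with Eef1a1 at 1.11 and Gusb at 1.08 (0.72 with normexp background). They stood apart with brightness matching (percentile 98.6) but not with size alone (percentile 77.5) or with normexp background. Of the lists that did not stand apart, 16 coupling genes had a median of -0.29 that turned to 0.07 under quantile normalization, with Sln at 2.20, Jph2 at -1.36 and Cav3 at -1.16 (-0.82 under quantile normalization). The median was 0.08 for 12 fibre type regulators (1 higher, 3 lower; Rcan1 -2.27 on 1 probe and -3.32 on another), and it turned to -0.07 with no filter on dim probes. For 21 autophagy genes (Wipi1 -1.67, Bnip3 -1.64) it was 0.12, and for 12 cell cycle genes (1 lower) 0.03. These and the medians of 7 lymphocyte markers (0.04, 1 lower) and 7 blood cell markers (0.20, none past 2-fold) turned negative with normexp background. None of 15 macrophage markers passed 2-fold (median 0.18). The clock list had 1 higher and 2 lower genes of 14 (median -0.30), with Bmal1 at -2.26 and -1.19 on its probes, Per1 at -1.49 (-0.91 with normexp background) and Per2 at 1.44. Of 15 immediate early genes 4 were lower (Nr4a1 -2.78, Dusp1 -1.74), and their median of -0.22 turned to 0.03 with the authors' values.

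Beyond the lists, the largest values on the high side were Tph1, the tryptophan hydroxylase of serotonin synthesis, at 6.84 and 5.79 on its probes, the cell adhesion protein Emb at 6.09, Ctxn3 at 5.99 and Lrrn1 at 5.57. On the low side they were the methyltransferase Mettl21c at -5.60, Wnt16 at -5.42 ± 0.89, Sbk2 at -5.05 on 1 probe and -3.38 on another, and Asb18 at -5.00. Bounds on the high side were at least 5.25 for Slc51a, 4.59 for the keratin Krt18, 4.47 for Unc13c and 4.40 for Lrtm2, while a second probe of each (-0.40 and -0.22) was above background on neither array. Those on the low side were -6.87 for SPATA45, -5.29 for Xrcc2, -5.16 for Gjd2 and -4.91 for Ropn1, and Xrcc2 and Gjd2 lay in bright patches of an array. The denervated array was alone on its slide, so denervation cannot be told apart from slide and scan. The balance of the counts depended on scaling and background, with 1568 higher and 1107 lower genes under the authors' values and 367 and 1001 with normexp background.

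The third comparison asks whether the genes that set denervated soleus apart were those that set plantaris apart. Of 10727 genes in both comparisons, 114 were at least 2-fold higher than normal soleus in both, among them Pvalb, Actn3 and Myh1, and 339 were lower in both, among them Ankrd2, against 35.5 and 95.2 for independent lists. Independence is no proper reference here, since both comparisons share the normal soleus array and with it that array's errors. In 1000 simulated sets of unchanged arrays, counted after the data were seen, repeat-spot noise alone put 99.3 genes higher and 99.5 lower in both on average (at most 127 and 128). With 1 pooled noise SD per array the averages were 6.9 and 6.8. The 114 lay within the first range and the 339 above it. The filter treats these counts unequally. A gene higher in both had to be well above background on the plantaris and the denervated array, a gene lower in both on the normal soleus array alone. The simulation did not apply this filter to its values. With no filter on dim probes, over more genes, 183 were higher in both. The kinase subunit Prkag3 (2.79 in plantaris, 3.06 in denervated soleus) was also higher in both, chosen after its values were seen. The counts depended on the treatment of faint probes. With bright patches left out 244 genes were lower in both, with normexp background 156, with signal on both arrays 169 and among agreeing repeat spots 122, and with normexp background 38 were higher in both.

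Some genes parted. There were 86 genes higher in plantaris and lower in denervated soleus, and 58 were lower in plantaris and higher in denervated soleus. Independent lists would give 71.9 and 47.0, but noise of the shared array moves both folds the same way and lowers such counts. The simulated unchanged arrays had at most 4 in each set, so repeat-spot noise alone does not account for the 86 and 58. Variation between animals, labellings or slides is not in the simulation. It cannot be measured with 1 array per group and stays open for these counts. There is also no proper reference for opposite moves among genes that do differ. Fbp2 stood at 3.47 and -2.77, and, chosen after their values were seen, the lactate transporter Slc16a3 at 3.36 and -4.27 and the water channel Aqp4 at 3.51 and -3.40. Sarcolipin, Sln, stood at -4.38 and 2.20 and Tnnt2 at -1.92 and 1.80. Set directly against plantaris, denervated soleus had all 14 fast fibre genes at least 2-fold lower (median -2.51) and 7 of 13 slow fibre genes higher and 1 lower (median 1.09). Glycolysis genes were lower in 21 of 23 (median -2.85) and respiratory chain genes in 18 of 20 (median -1.68). Of 11083 genes, 684 were at least 2-fold higher in denervated soleus than in both normal muscles and 1033 lower than in both. These folds share the denervated array, and unchanged arrays simulated after the data were seen, with repeat-spot noise only, had at most 76 and 72.

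**Figure D4:**
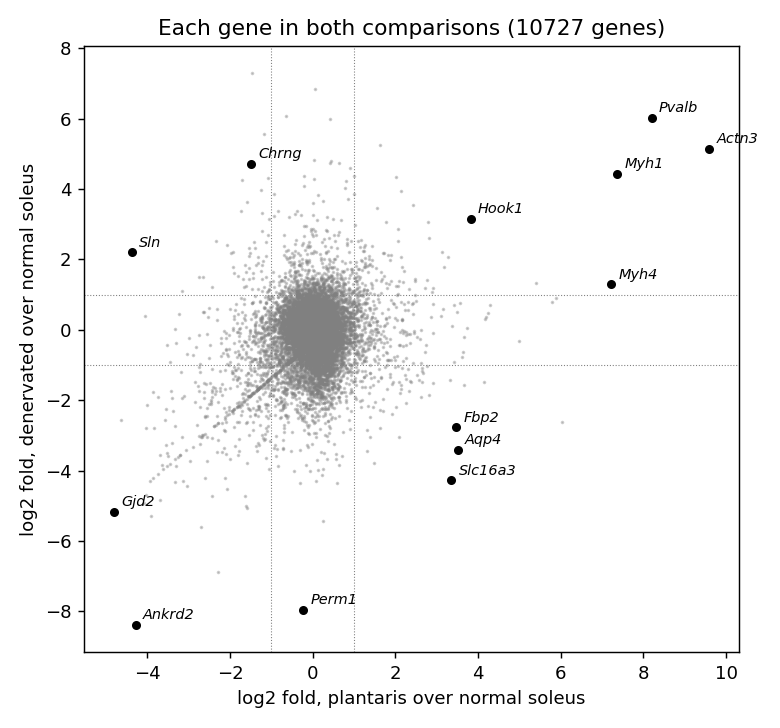
Log2 fold of each of 10727 genes in plantaris over normal soleus (horizontal axis) and denervated over normal soleus (vertical axis), with dotted lines at 2-fold and 13 genes marked. Pvalb, Actn3 and Myh1 lie high in both, Ankrd2 low in both, and Fbp2 and Sln in opposite corners.

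Across genes, which are not independent replicates, the folds of both comparisons correlated at r = 0.229. Simulated unchanged arrays that share the soleus array's noise gave 0.694. Differences that the comparisons do not share lower r in advance, so no conclusion is drawn from this gap. The covariance of the folds was 0.162, against 0.0994 in 1000 simulated sets, or 0.0743 with 1 pooled noise SD per array.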

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

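No test of an explanation was run on the count in this part, which comes from probes that the comparisons leave out. Of the 12362 probes without a gene symbol, 7530 were well above background on the denervated array, and 655 of these (8.7%) were at least 2-fold higher there than on the normal soleus array. Of the 12807 probes with a symbol and signal well above background there, 1148 (9.0%) were, so the share was much the same. The probes without a symbol could not be joined to a gene in the reference used here. No biological explanation was tested.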

How the results depend on the processing

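Settings that left out bright patches or kept only agreeing repeat spots were chosen after the results were seen, and the rest were planned. No paired analysis was possible because there is 1 array per group, and for the same reason leaving out a replicate, treating the slide as a block and splitting the samples otherwise could not be run. Over the alternatives, 580 list medians kept their side of the limits, 13 newly stood apart and 7 no longer did. Of all 600, 30 changed sign, none in a list reported as standing apart. Of the gene counts 26 stayed within 1.5 times the reported count and 18 did not, and of the overlap values 32 did and 13 did not. Every gene count at the 1.5-fold and 4-fold thresholds was among those 18. Of the values of named genes 2253 lay within the scanner error of the reported fold, 326 lay further off and 1 reversed. The filters on dim probes cannot move the value of a gene measured on both arrays, so part of the 2253 is fixed by construction. The reversed one was Cdkn1a in denervated over normal soleus, at 2.14 as a mean of its probes, which stand at -1.04 and 5.33. Among all genes past 2-fold, Elf5 with bright patches left out and Prima1 among agreeing repeat spots also changed direction in denervated soleus, both named after their values were seen.

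Normexp background gave 309 higher and 282 lower genes in plantaris and 367 and 1001 in denervated soleus, with overlaps of 38 (higher in both), 52 (higher in plantaris, lower in denervated soleus), 21 (the reverse) and 156 (lower in both). It kept 587 of the 1302 calls in plantaris and 1358 of 2506 in denervated soleus, turned none, and by construction it shrinks the folds of faint probes. There the denervated immediate early median was -0.50 and newly apart, and the reference gene median was 0.14 and no longer apart. Under quantile normalization the reference genes in plantaris (-0.38) and the endothelial markers in denervated soleus (-0.53) stood apart, and the cause was not tested.

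Requiring signal on both arrays leaves fewer genes, with 433 lower in plantaris, overlaps of 37 (lower in plantaris, higher in denervated soleus) and 169 (lower in both) and a correlation of 0.135. The cell cycle median in plantaris (-0.36) no longer stood apart there, while the lymphocyte (-0.48) and smooth muscle (-0.33) medians in plantaris and the Schwann cell median in denervated soleus (-0.48) did. Without a filter 183 genes were higher in both. The authors' values, which add 1 constant per array to every log2 fold, gave 1568 higher genes in denervated soleus.

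As a mean of a gene's probes, the fibre type regulators (0.51) and lymphocyte markers (-0.48) in plantaris newly stood apart and the clock list (0.19) no longer did. With bright patches left out the lymphocyte median in plantaris (-0.48) and the endothelial median in denervated soleus (-0.48) newly stood apart. Agreeing repeat spots alone, a smaller set of genes, gave 365 higher and 315 lower genes in plantaris, 562 and 895 in denervated soleus, overlaps of 69 (higher in both), 55 (higher in plantaris, lower in denervated soleus), 37 (the reverse) and 122 (lower in both) and a correlation of 0.124. There the cell cycle median in plantaris (-0.30) no longer stood apart, and the immediate early (-0.69) and endothelial (-0.48) medians in denervated soleus did. Beside random lists matched on size alone, the lymphocyte median in plantaris (-0.48) stood apart, and in denervated soleus the fast fibre (0.27), smooth muscle (-0.56) and reference gene (0.20) medians no longer did. The cause of these list changes was not tested.

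At 1.5-fold there were 1430 higher and 1395 lower genes in plantaris and 2237 and 2571 in denervated soleus, and at 4-fold 149, 166, 210 and 375 in that order. Signal over background limits the counts, since genes with a mean signal below -3 log2 units made up 32.1% of those compared in denervated soleus, 56.0% of the higher and 41.7% of the lower ones.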

Other observations

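Tests on mitochondrial genes, clock genes and bright patches, and the choice of gene families and of the genes named in this part, came after the results were seen. The tests on a second fat cell list and on a second list of gene families drawn by symbol were written before their values, apart from Lpl and Magea13, which had been seen. In all, 5 patterns were tested, and no p-value is possible with 1 array per group.

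Among 15 gene families looked at by symbol, 4 belong to the mitochondrion, and 2 of them had several genes at least 2-fold lower and none higher in denervated soleus. Of 38 genes of complex I subunits and assembly 23 were at least 2-fold lower and none higher (median -1.15), as were 16 of the 31 that the respiratory chain list does not hold (median -1.04). Of these 31, 8 were lower with the authors' values (median -0.794) and 9 under quantile normalization (median -0.695). Of 66 mitochondrial ribosomal proteins 13 were lower and none higher (median -0.62). In the other 2, mitochondrial carriers had 7 of 30 lower and 1 higher (median -0.39) and mitochondrial aminoacyl-tRNA synthetases 1 of 14 lower (median -0.69). The medians of complex I and of the mitochondrial ribosomal proteins stayed below 0 under every alternative for scaling, background, filter and probes, at -0.77 and -0.44 under quantile normalization, but with the authors' values only 14 of 38 and 5 of 66 were lower (medians -0.91 and -0.38). Cytosolic ribosomal proteins had a median of 0.00 over 79 genes, but 0.56 under quantile normalization. Within that family Rpl3 stood at 1.22 and its muscle-specific relative Rpl3l at -1.18 in denervated soleus, against -0.49 and 0.45 in plantaris. Rpl3 kept its 2-fold difference under every scaling tried, and Rpl3l did not, at -0.94 with the authors' values and -0.88 under quantile normalization.

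Tissue kallikreins, serine proteases that release kinins, were well above normal soleus on the denervated array. Klk1 stood at 4.74 ± 0.20, Klk1c2 at 4.80 ± 0.21 and Klk1c8 at 4.75 ± 0.22, against 0.42, 0.43 and 0.63 in plantaris. The lowest of their values over all alternatives was 3.85, for Klk1c8 with normexp background. These genes are close paralogs, so their probes need not be independent. Of 8 measured members of the family 4 were higher and 2 lower (median 1.88, or 0.52 with normexp background). Of 58 potassium channel genes 5 were higher and 19 lower (median -0.61), but 3 and 9 with normexp background and 3 and 11 of 42 with signal on both arrays. Kcnf1 stood at 3.33 and Kcnj13 at -4.32, or 1.84 and -3.19 with normexp background. In plantaris Kcnj13 was lower too (-3.33), and Kcnf1 was at a bound of -1.23 (-0.16 with normexp background). Neither gene was kept among agreeing repeat spots, and Kcnf1 was at 4.445 in denervated soleus with bright patches left out.

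The lower mitochondrial genes in denervated soleus were set against 2 explanations, a change in tissue and a technical one. The list medians were already known, so the outcome of the first comparison was fixed beforehand, and genes of 1 array are not replicates. A smaller share of muscle fibre RNA in the sample would lower other fibre genes alike, but the median of the excitation-contraction coupling list lay 1.25 log2 units above that of the respiratory chain list (bootstrap interval over genes 0.87 to 1.61). A change in signal scale between the slides would lower spike-ins of the same brightness alike, but these differed by -0.265 on average (3 levels, -0.39 to -0.19), against a list median of -1.54. The coupling comparison draws no verdict on fibre share, since its outcome was known and fibre lists moved unlike each other. The slow fibre list fell about as far as the respiratory chain list (median -1.5). Fat cell and fibroblast markers rose (1.70 and 0.80), so a smaller fibre share stays open. The spike-in values argue only against a uniform change in signal scale as the whole cause, at the 3 levels they cover. Loss of the nerve was not tested as a cause, and a slide effect specific to some genes cannot be told apart from it with 1 array per slide.

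The 339 genes lower than normal soleus in both comparisons may come in part from the array they share. Among those with 1 spot per probe, 17 of 85 (20%) lay in a bright patch of the normal soleus array, against 1.78% of 1913 others, a ratio of 11.3. Among faint genes alone it was 28.8% of 52 against 1.4% of 568. With bright patches left out the count was 244, so patches over the cutoff of 1 log2 unit can account for a part of this pattern only. Weaker local brightness stays in that count and was not tested. The noise of the shared array beyond patches and a slow muscle programme lowered in both, as for Ankrd2, both stay open.

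Olfactory, vomeronasal and taste receptor probes were lower in denervated soleus, with 109 of 244 at least 2-fold lower and 12 higher (median -0.87; 0.20 in plantaris), but 51 of 245 and 1 with normexp background (median -0.59), and 49 and 1 of 106 with signal on both arrays. To see whether faint signal unrelated to the gene was weaker on the denervated array, a second list of families was drawn by symbol, and it had a median of -0.711 over 91 genes, 31 lower and 3 higher. This met the bound of -0.5 written beforehand. The list also took in broadly expressed genes such as casein kinases, so it is no clean list of silent genes. Of these 18 were recognised after the test, and the median was -0.86 without them. The 3638 faint genes that passed the filter had a median of 0.09, so these were not lower in general. The filter leaves out the dimmest genes. With no filter on dim probes the median of all 15168 genes was -0.108. That of 1295 receptor genes was -0.428 there, with 212 lower and 40 higher. The condition on faint genes was added after the second list was seen to meet its bound, and with it the test leaves the matter open. Against plantaris the receptor probes stood at a median of -1.05 on the denervated array, and the slide cannot be told apart from denervation.

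The second fat cell list had a median of 0.931 in denervated soleus, with 8 of 18 genes higher and 4 lower, Slc7a10 at 3.12 and Aqp7 at -2.80, which falls short of the 1 log2 unit set beforehand. The bound set against fat cell RNA, a median below 0.5 with an upper quartile below 1, was not met either (upper quartile 1.99), so this test leaves it open. Of the clock genes, Bmal1, Clock, Npas2 and Cry1 had a median of -0.63 and Per2, Per3, Dbp, Tef, Nr1d1, Nr1d2 and Ciart of 0.44, a difference of -1.068 log2 units. These arms left out Per1 (-1.49), Cry2 (-0.87) and Bhlhe40 (0.22). The difference was -0.79 with Per1 in the second arm and -0.68 with all 3 there, and with 1 array per group the hour of sampling cannot be told apart from the operation.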
